A study of Mus musculus with 37 samples.

How the data were processed

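The series holds 37 RNA-sequencing libraries from microdissected mouse bladder urothelium. Per the labels' protocols, RNA was extracted with a kit for formalin-fixed, paraffin-embedded tissue and libraries were made with a low-input kit. The submitters' processing notes name STAR 2.5.0, featureCounts and DESeq2, without saying how each was used. They give the genome build under the names mm10 and GRCm38.

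The expression values were not analysed here. The authors deposited 1 table of whole numbers and 1 table of normalized values for the whole series. Each has 37 value columns, named only by a running number. None of these names occurs in the labels of any sample or in the other deposited files, so 37 columns of each table were left unmatched and unused. Assigning them by column order or by their values would have been a guess at which library came from which lesion. For the same reason no depth per library, no gene test, no gene list and no named gene is given, and the planned edgeR comparisons were not run.

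What could be tied to samples by name was the set of labels and the list of sample plates and index sequences. The other, non-numeric values used were the plate names and index sequences as deposited by the authors, in a list whose rows carry the sample titles. Each library was placed in a stage group by its tumour stage label, and its histological differentiation, week of sampling and mouse were taken from the labels.

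The label comparisons and their alternatives were written after the labels and the list of plates had been read, in place of the gene tests fixed before the data were examined. They describe values that were already known, set by how the authors chose and laid out the lesions, so they are given as counts, means and SD without p-values. Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1 were used. Lesions of the same mouse were counted separately. Alternatives kept 1 lesion per mouse and stage, left out the mouse with 3 lesions, used a single plate, or left out each library in turn. The authors chose the lesions to cover the stages, so shares and weeks describe this collection and not how often or when a lesion arises.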

Results

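The collection covered bladder carcinogenesis induced by N-butyl-N-(4-hydroxybutyl)-nitrosamine (BBN), a bladder carcinogen, in male C57BL/6 mice. Exposed animals were 8 weeks old at the start and drank water with 0.05% BBN for up to 14 weeks. The question, as the series title states it, was which molecular changes accompany progression of basal/squamous and sarcomatoid bladder tumours. The 37 libraries came from 31 mice and fell into 8 groups. There were 5 control urothelia from unexposed mice, 3 urothelia of normal morphology from exposed mice, 4 hyperplasias, 5 dysplasias, 3 carcinomas in situ (CIS, flat non-invasive tumours), 5 pTa tumours (papillary, non-invasive), 7 pT1 tumours (invading the lamina propria) and 5 muscle-invasive bladder cancers (MIBC). Expression values are not reported, because the columns of the deposited tables were not matched to these samples by name, and the transcriptional comparison of the stages was not analysed here.

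Most early lesions were labelled urothelial and no tumour was. Of the 9 hyperplasias and dysplasias, 7 were labelled urothelial and 2 squamous, 1 of each stage. All 20 tumours were labelled squamous or sarcomatoid. The 3 CIS and the 5 pTa tumours were squamous. Among the 7 pT1 tumours 4 were squamous and 3 sarcomatoid, and among the 5 MIBC 4 were squamous and 1 sarcomatoid. A sarcomatoid tumour is a carcinoma with spindle-cell, mesenchyme-like morphology. Squamous or sarcomatoid differentiation was thus recorded in 100% of tumours and in 22.2% of hyperplasias and dysplasias, a difference of 77.8 percentage points. On the first sample plate the counts were 15 of 15 tumours and 0 of 2 early lesions, and on the second 5 of 5 and 2 of 7.

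The stages were sampled at different times after the start of exposure. Normal urothelium of exposed mice and hyperplasia came from weeks 2 to 8, and dysplasia from weeks 12 to 16. CIS spanned weeks 8 to 16, pTa weeks 12 to 16, pT1 weeks 12 to 24 and MIBC weeks 16 to 24. Exposure lasted up to 14 weeks, so all MIBC, and the other lesions from week 16 onward, were sampled after it had ended. Stage was therefore not separated from whether exposure had ended. Controls were taken at weeks 8 to 24, with 1 mouse at each of 5 times and none at week 2. Invasive tumours (pT1 and MIBC) were sampled at 19 ± 4.22 weeks (SD, n = 12) and non-invasive tumours (CIS and pTa) at 13.5 ± 2.98 weeks (SD, n = 8). The means lay 5.5 weeks apart, and both groups had tumours from weeks 12 and 16. On the first plate alone the means were 19 weeks for 12 invasive tumours and 13.3 weeks for 3 non-invasive tumours. The second plate held no invasive tumour.

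The sampling times of sarcomatoid and squamous invasive tumours overlapped. The 4 sarcomatoid tumours were taken at 18 ± 5.16 weeks (SD, n = 4) and the 8 squamous tumours at 19.5 ± 3.96 weeks (SD, n = 8), a difference smaller than either SD. Without pT1 replicate 1, a sarcomatoid tumour from week 12, the difference changed from -1.5 to 0.5 weeks. The mouse with 3 lesions gave 1 sarcomatoid and 2 squamous invasive tumours, all from week 16, so it lies in both groups. Without that mouse the difference was -2 weeks. All 12 invasive tumours lay on the same plate.

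Stages were unevenly spread over the sample plates. The first plate carried 22 libraries and the second 15, and the plates split the libraries exactly as the series prefix of the source names did, in 37 of 37 cases. All 5 controls were on the first plate and all 3 normal urothelia of exposed mice on the second. All 12 invasive tumours were on the first plate, against 3 of 8 non-invasive tumours, or 37.5%. Hyperplasia, dysplasia, CIS and pTa had libraries on both plates, with 1, 1, 1 and 2 of them on the first. Exposure in normal-looking urothelium and plate therefore cannot be separated within those 2 groups alone, whereas sarcomatoid and squamous invasive tumours share a plate. The exposed normal urothelia and the controls also differed in week, at weeks 2 to 8 and weeks 8 to 24. The plates had 5 index sequences in common.

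Several mice gave more than 1 library. The 29 lesions came from 26 mice by their mouse labels, whereas the series design text counts 27, and the difference was not resolved. In 3 mice hyperplasia and urothelium of normal morphology were both sampled. In 1 of these mice the hyperplasia was on the first plate and the normal urothelium on the second. The other pairs lay wholly on the second plate. A further mouse gave 2 dysplasias, and another gave 3 tumours, a sarcomatoid MIBC and 2 squamous pT1.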

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

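No paired analysis was possible because no expression column was matched to a sample. The alternatives planned for the gene tests were not run for the same reason. All alternatives given here, like the label comparisons they apply to, were chosen after the labels had been read. They describe the collection, and the p-values computed for them are not given. On the first plate alone, invasive and non-invasive tumours lay 5.67 weeks apart, with 3 non-invasive tumours left, and over the other alternatives 4.71 to 6.5 weeks apart. Sarcomatoid and squamous invasive tumours differed by -3.5 to 0.5 weeks when each was left out, with a positive value only without pT1 replicate 1. The share of squamous or sarcomatoid lesions was higher in tumours by 71.4 to 100 percentage points over its alternatives, the ends being the second and the first plate alone. Every tumour was squamous or sarcomatoid, so leaving out a tumour could not change that share. Controls and normal urothelia of exposed mice differ by 100 percentage points in their first-plate share whichever library is left out. Each of these groups lay wholly on a single plate, so leaving out a library could not change this difference.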
